A study of Arabidopsis thaliana with 4 samples.

How the data were processed

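Total RNA of whole Arabidopsis thaliana seedlings was measured on 4 one-colour Agilent expression arrays, 2 for the wild type and 2 for the ced2 mutant. Per the labels, each RNA came from 20 pooled plants, 0.3 µg of RNA was labelled with the dye Cy3, and the replicates of a genotype are biological. Per the submitters' processing notes, the scans were read with Agilent Feature Extraction 10.7.1.1. Per the file headers, the deposited scanner files hold one intensity per spot (the processed signal, a background-subtracted and spatially detrended brightness on a linear scale), the median intensity of each spot and of its local background, and flags for spots that are well above background, saturated or outliers. These intensities had not been normalized between arrays. The authors' value table holds log2 values, and the files do not state how it was scaled or centred. Set against the scanner files, it proved to be the log2 processed signal minus the array's 75th percentile, with each probe's median over the 4 arrays moved to 0. The column medians were 0.08 and -0.03 for the columns labelled WT replicates 1 and 2, and 0.01 and -0.03 for those labelled ced2. The genotype that belongs to each column stays unsettled, because every column held the values of a scanner file labelled with the other genotype.

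The main values were log2 of the processed signal minus each array's 75th percentile of it over the probes used. Control spots and outlier spots were left out, and 70 of 43603 probes, which lost all their spots on an array, were dropped, which left 43533. Spots of one probe were averaged. Probe accessions were matched without versions to a RefSeq gene table of the assembly TAIR10.1, which was used for names and gene order alone. Of the probes, 34236 had a gene and 9297 had none in that table, and these were not tested. The array header names an older build, so no coordinates are given. The 25356 genes were each represented by the probe with the highest mean signal, a rule that mattered for the 6903 genes with more than 1 probe. A gene was tested where that probe was well above background on both arrays of at least 1 group, which held for 20837 genes. Folds marked "at least" belong to genes whose probe was not well above background on either array of a group. For FLC, dim on 1 array of a group, the fold is marked in the same way. There the bright group's mean was set against the mean, per array, of the higher of the dim probe's own signal and the lowest signal among probes well above background. On some arrays the dim probe's own signal was the higher and was used. This was so for GLC, AT2G04190, GASA2, IPT7, NRT2.1 and PR1. Their folds are partly or wholly measured ratios and not strict bounds.

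The groups were compared with limma 3.58.1 (lmFit and eBayes, R 4.3.3) as ced2 files minus WT files, two-sided, and every adjusted p of a gene is limma's with Benjamini-Hochberg adjustment over all genes tested. The threshold was an adjusted p of 0.05, with a 2-fold minimum for a second count. The fit had 2 residual degrees of freedom and an estimated 1.49 from the prior. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 21 lists with at least 3 measured genes. All 22 lists and 280 list genes were fixed before the data were examined, and 279 of them were on the array. Counts within a list are given over all genes and adjusted over the list alone.

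The genes named in the report follow a rule that was also fixed before the data were examined. It takes NCED3, VSR1 and BDG1, then the 8 genes with the highest and the 8 with the lowest log2 difference among those past the threshold whose groups do not overlap, then up to 4 members past the threshold, by smallest p, of each list that passed camera and of both abscisic acid lists named in the design. That gave 53 genes, 2 of them under more than 1 part of the rule, and 1 of the 53 is not reported here. Members of other lists, and further members of these, are named with their values as examples chosen after the values were seen.

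Alternatives fixed before the data were examined were quantile normalization, normexp background correction with an offset of 50, no filter on dim probes, a filter that asks for all 4 arrays, the authors' value table, the mean over a gene's probes, the replicate number as a block, an intensity trend in eBayes, an adjusted p of 0.01, camera with an estimated correlation, fry, and leaving out each array. Normexp was run on the median spot intensity, since the files carry no mean intensity. With an estimated correlation, camera takes its p from the 2 residual degrees of freedom, so a list could hardly pass. Slide could not be fitted as a block, because all 4 arrays lay on 1 slide and were scanned at 1 time. The WT arrays lay at positions 1 and 2 of the slide and the ced2 arrays at positions 4 and 3, so position and genotype cannot be told apart.

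The fit and the list test were tested on simulated data, for the ced2 minus WT comparison with 20837 genes and 200 changed ones. Of 63 genes changed 4-fold, 93.7% were called in the right direction. Of 73 genes changed 2-fold, 84.9% were called, and of 64 genes changed 1.19-fold, 0% were. There were 2 false calls among 123, and the 1 list raised in the simulation was the 1 list of 21 past the threshold. Noise was drawn independently for each probe, so the simulation could not test the preset correlation between genes. Far more genes, 16239, passed in the data, which eases the adjustment, so the 0% at 1.19-fold does not carry over. BCH2, for example, passed with a log2 difference of 0.12 (limma adjusted p = 0.0129). Figures were drawn with matplotlib 3.10.9, and the scanner files were read with Python 3.11.15 and pandas 2.3.3.

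Between 73.8% and 77.9% of the 43803 non-control spots of an array were well above background, and 0 spots were saturated. The number of arrays, 2 per genotype, limits the precision. Untreated seedlings were not analysed here, so no value below is a response to the treatment.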

Results

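Gene expression under osmotic stress was compared between ced2, an Arabidopsis mutant, and its wild type, a line that carries luciferase driven by the NCED3 promoter in a gl1 Columbia background. Seedlings grown for 14 d were moved to a solution of 40% polyethylene glycol (PEG), which withdraws water from tissues, for 6 h before whole seedlings were harvested. There were 2 arrays per genotype. The median processed signal was 405 and 341 on the WT arrays (replicates 1 and 2) and 524 and 630 on the ced2 arrays, and the 75th percentile over non-control spots was 3322, 2790, 3710 and 4444 in the same order. The series asked which genes of the osmotic stress pathway were affected in the mutant.

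NCED3, which encodes the dioxygenase that cleaves carotenoid precursors in the committed step of abscisic acid (ABA) synthesis, fell by 1.33 on the log2 scale in the arrays whose files are labelled ced2, a level 2.51-fold below that of the WT files (SE 0.0231, n = 2 per group, limma adjusted p = 0.000161). Its normalized log2 signal was 0.67 ± 0.01 (SD, n = 2) in the WT files and -0.66 ± 0.02 in the ced2 files. Of the 22 measured genes that respond to ABA and dehydration, 21 fell, as did 16 of 25 core ABA signalling genes, while all 8 measured DREB and ZAT stress transcription factors rose. The sign of every difference depends on which deposited labels are followed. In the authors' value table, the same measurements carry the opposite genotype labels: each of its 4 columns matched a scanner file of the other genotype with r = 0.999999 across probes, and 100% of its values lay within 0.01 of that file's centred values. The correlations with the scanner file of the column's own sample lay between -0.573 and -0.369. Under the value table's labels NCED3 would be higher in ced2, by 1.33. Directions below follow the scanner files, as fixed before the data were examined, and "ced2 files" and "WT files" refer to their labels.

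**Figure D1:**
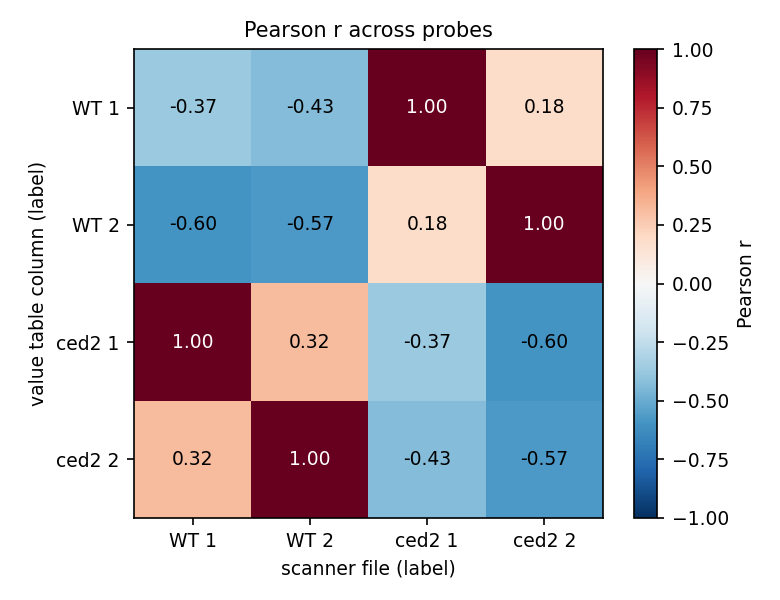
Pearson correlation across probes (colour and printed value) between each column of the authors' value table (rows, by label) and each scanner file (columns, by label), both centred per probe over the 4 arrays. Each column matched a file of the other genotype at r = 0.999999 and none matched its own.

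Over all genes, 16239 of 20837 passed the threshold, of which 8830 were higher and 7409 lower in the ced2 files, and 4598 did not pass. At a minimum of 2-fold, 1668 were higher and 692 lower, so that 70.7% of these calls were higher. The split was 1294 against 821, or 61.2% higher, with quantile normalization. With normexp background correction it was 616 against 554, or 52.6% higher. At 4-fold, 269 genes were higher and 137 lower. Replicate arrays differed by very little: the median absolute log2 difference was 0.0456 between the WT arrays and 0.034 between the ced2 arrays, against 0.351 to 0.356 between genotypes. The p-values rest on that spread, which was no larger than the spread of repeat spots within an array.

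**Figure D2:**
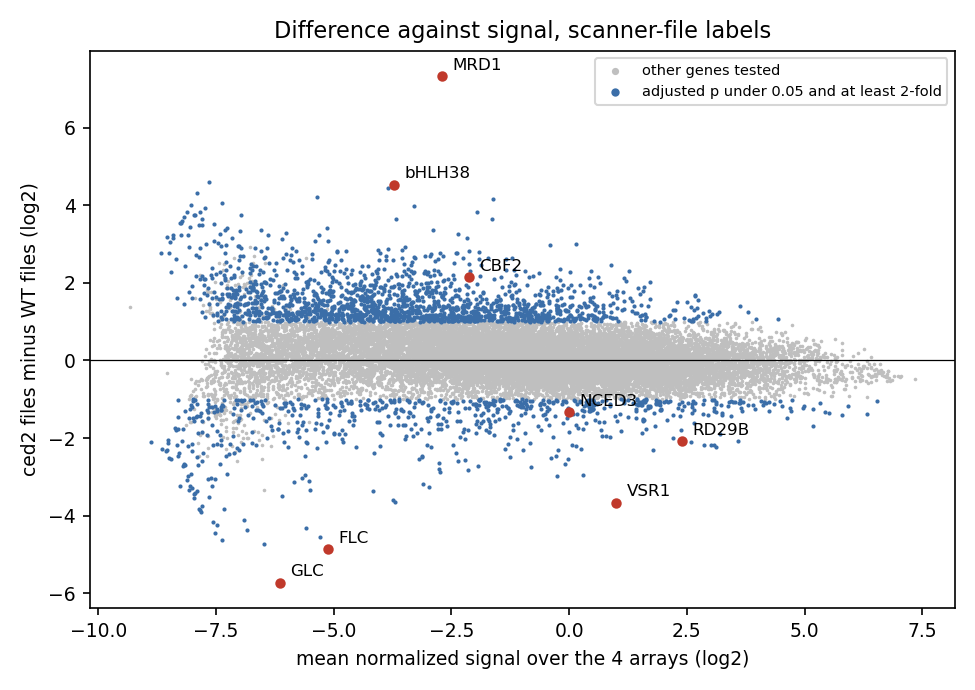
Log2 difference (ced2 files minus WT files, vertical) against the mean normalized log2 signal (horizontal) of the 20837 genes tested, with the 1668 higher and 692 lower genes past the threshold and at least 2-fold in blue and 8 named genes in red. MRD1 stands highest at 7.33, genes with a dim group, such as GLC (at least 37.7-fold lower), are drawn at their measured signal, and under the authors' value table every sign would turn.

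Among the 8 highest genes, transcripts of bHLH38 and bHLH39, neighbouring basic helix-loop-helix regulators of iron uptake, rose by 4.54 and 4.45 on the log2 scale (23.2-fold and 21.9-fold, adjusted p = 0.00016 for both), CYP82C4, a cytochrome P450, rose by 4.21, and AT1G47395 rose by 4.17. MRD1 rose the most, from a log2 signal of -6.37 ± 0.02 (SD, n = 2) to 0.96 ± 0.01, or 161-fold (adjusted p = 0.00016). These sizes depend on the background correction: with normexp MRD1 rose by 5.51, bHLH38 by 3.13, bHLH39 by 2.94, CYP82C4 by 1.85 and AT1G47395 by 3.70. The other 3 of the 8 were not well above background in either WT file: AT3G56180 was at least 13.4-fold higher (adjusted p = 0.00671; its ced2 arrays lay apart, at -6.58 and -4.90, and without replicate 2 the bound was 7.47-fold) and IPT7, an isopentenyltransferase of cytokinin synthesis, at least 16.7-fold (adjusted p = 0.000228), and the bound for CYP76C7 lay above both (adjusted p = 0.00129). These 3 bounds hold for the main setting alone, and the calls were lost with normexp, where the genes rose by only 0.271, 0.387 and 0.375 on the log2 scale (adjusted p between 0.56 and 0.724), and a second probe of CYP76C7 and of AT3G56180 was dim on all 4 arrays. The call of AT3G56180 also ended without either WT array (adjusted p = 0.0502 and 0.0503).

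Among the 8 lowest genes was FLC, the repressor of flowering that vernalization silences. The probe that represents it, with the highest mean over the 4 arrays, was at least 21.0-fold lower (adjusted p = 0.0274) and dim on ced2 replicate 1, without which it fell by 3.29; the remaining probes were brighter on the WT arrays and dim on both ced2 arrays, each at least 88.7-fold lower. GLC was at least 37.7-fold lower (adjusted p = 0.00872), and leaving out either WT array ended this call (adjusted p = 0.0595 and 0.0596) and that of FLC (adjusted p = 0.124 and 0.121), which was also lost without a filter on dim probes (adjusted p = 0.0587). GASA2, of a gibberellin-regulated family, was at least 15.8-fold lower, AT2G04190 at least 20.4-fold and AT5G44973 at least 12.6-fold, with a smaller bound for AT3G45510 (adjusted p between 0.00016 and 0.0027 for all 4). These bounds hold for the main setting alone: with normexp the 4 fell by 1.914 to 2.195, and GLC and FLC by 2.91 and 2.92. Without ced2 replicate 2 the bound for GLC was 22.7-fold. HSD1, a hydroxysteroid dehydrogenase, fell by 4.32, and AT2G02720 fell by 4.55; both were above background on 1 ced2 array, and with normexp they fell by 2.67 and 3.02. The pairs bHLH38 and bHLH39, and GASA2 and its neighbour GASA3, are similar in sequence, and probes may not separate such copies.

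In the ABA biosynthesis list, 7 of 12 measured genes fell, 3 rose and 2 did not pass, and 11 passed when adjusted over the list alone against 10 over all genes. Besides NCED3, ABA3, the molybdenum cofactor sulfurase, fell by 0.79 (adjusted p = 0.000225), and BGLU18, a glucosidase that frees ABA from its glucose ester, fell by 1.00 (adjusted p = 0.000251). ABA2, the dehydrogenase that makes abscisic aldehyde, went the other way and rose by 0.52 (adjusted p = 0.000563). The list as a whole had a median of -0.21, or -0.487 with normexp, and did not pass camera in either setting (adjusted p = 0.255 and 0.127). Of 6 genes of ABA catabolism and conjugation, 3 fell, 1 rose and 2 did not pass (4 adjusted over the list alone); CYP707A2, an ABA hydroxylase, fell by 2.18, and the list did not pass (median -0.17, or between -0.272 and -0.107 with 1 array left out; adjusted p = 0.178).

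The genes that respond to ABA and dehydration fell as a group, with a median of -0.52, or -0.299 with quantile normalization (camera adjusted p = 1.91e-05 in the main setting; adjusted p = 0.536 with an estimated correlation). Of the 22, 21 fell and 1 did not pass, and all 22 passed when adjusted over the list alone. RD29B fell by 2.08, EM1, a late embryogenesis abundant gene of seeds, by 1.68, LEA4-5 by 1.43 and RD22 by 1.31 (adjusted p between 0.000168 and 0.000316). KIN2 was the member that did not pass (-0.39, adjusted p = 0.057). Some bright genes outside the list were lower by as much as its smaller falls. UBQ10, PSBO1 and LHCB1.3 were lower by 0.39, 0.39 and 0.43, against 0.43 for COR47 and 0.44 for ERD10. The bright genes EF1A and GSTU19 differed by only -0.02 and -0.03. With quantile normalization the list's median moved from -0.52 to -0.299. The photosynthesis list moved from -0.28 to 0.05 and the aquaporins from 0.13 to 0.347, also upward. The size of the smaller falls therefore depended on the scaling between arrays. How much signal strength adds to each of them was not tested. The call of EM1 was lost when its probes were averaged (-0.63, adjusted p = 0.24).

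**Figure D3:**
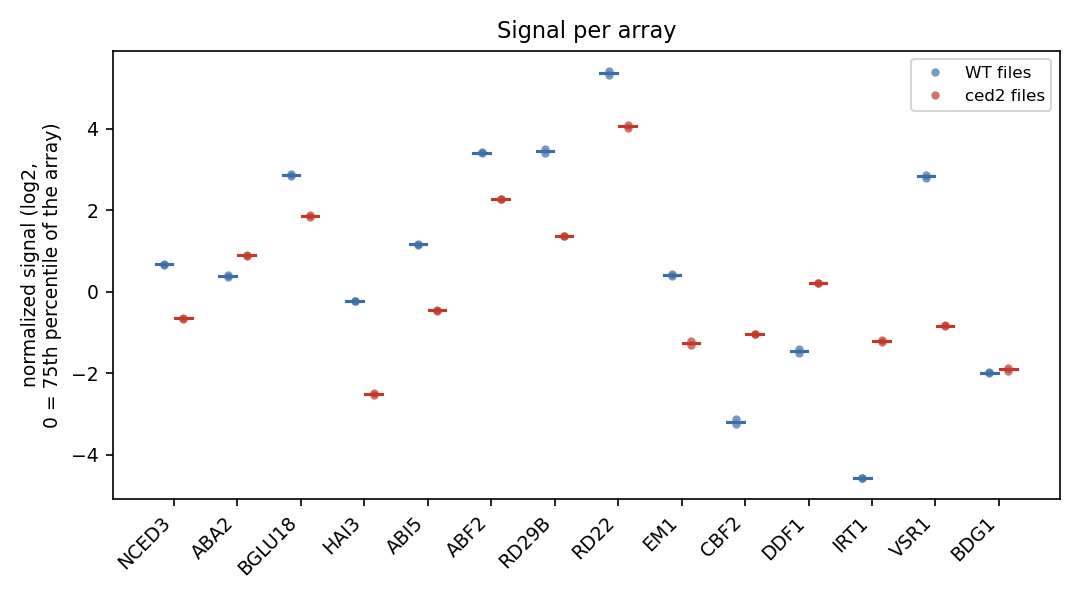
Normalized log2 signal of 14 named genes on each array (points; 0 is the array's 75th percentile), with blue for the 2 WT files, red for the 2 ced2 files and bars for group means. NCED3 lay at 0.67 in the WT files and -0.66 in the ced2 files, and BDG1 differed by only 0.08; the authors' value table gives the groups the opposite labels.

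The core ABA signalling list fell with a median of -0.56 (camera adjusted p = 0.0144; adjusted p = 0.385 with an estimated correlation), with 16 of 25 genes lower, 6 higher and 3 not past, and 22 past adjusted over the list alone. The phosphatases HAI3 and ABI2, which restrain ABA signalling, fell 4.91-fold and 2.32-fold, and the transcription factors ABI5 and ABF2 fell by 1.62 and 1.13 (adjusted p between 0.00016 and 0.000179). The 6 that rose were all ABA receptors, among them PYL4 at 0.91 and PYL2 at 0.86, whereas the receptor PYR1 fell by 0.30.

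The DREB and ZAT transcription factors rose in 8 of 8 members, also adjusted over the list alone, with a median of 0.98 (camera adjusted p = 0.0143; adjusted p = 0.385 with an estimated correlation). CBF2, a regulator of cold acclimation, rose by 2.15, DDF1 by 1.69, DREB1A by 1.12 and ZAT12 by 0.97 (adjusted p between 0.000186 and 0.000368). Their near copies CBF1, CBF2 and DREB1A may share hybridization. All 10 measured genes of the unfolded protein response rose, also adjusted over the list alone, by a median of 0.46 (camera adjusted p = 0.0116; adjusted p = 0.385 with an estimated correlation). Apart from the transcription factor BZIP60, which rose by 0.28, they are chaperones and folding factors of the endoplasmic reticulum. Of these, CRT1 rose by 0.74, CNX1 by 0.68, BIP2 by 0.56 and ERDJ3B by 0.51. Of 12 heat shock genes 10 rose and 2 fell (12 adjusted over the list alone), with a median of 0.64 (camera adjusted p = 0.0258; adjusted p = 0.385 with an estimated correlation). HSP21 rose by 1.39, HSP17.6II by 1.11, HSP23.6 by 1.00 and HSP18.2 by 0.96, and HSP22.0 fell by 0.61.

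Auxin-responsive genes rose in 7 of 9 measured members and 2 did not pass (7 adjusted over the list alone), with a median of 0.45 (camera adjusted p = 0.0258; adjusted p = 0.385 with an estimated correlation). IAA5 rose by 1.70, GH3.3 by 0.94 and IAA19 2.14-fold. Root and root hair markers, which stand for the root in whole seedlings, rose in 8 of 10 members, fell in 1 and did not pass in 1 (9 adjusted over the list alone), with a median of 0.82 (camera adjusted p = 0.0258; adjusted p = 0.385 with an estimated correlation). IRT1, the iron transporter of root epidermis, rose by 3.37, COBL9 by 1.76 and EXPA18 by 1.61, while the nitrate transporter NRT2.1 was at least 3.19-fold lower, a call lost with normexp (adjusted p = 0.0915). The list's call was lost without IRT1 (median 0.74, adjusted p = 0.0511) and when probes were averaged (adjusted p = 0.0587). With normexp the median was 0.53, IRT1 rose by 2.45 and EXPA18 by 0.948. These root markers moved with the genotype beside every group described here.

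VSR1, a vacuolar sorting receptor, was 12.7-fold lower in the ced2 files: its log2 signal fell by 3.67, from 2.83 ± 0.05 (SD, n = 2) to -0.83 ± 0.02 (adjusted p = 0.00016). In the vacuolar sorting list 8 of 14 measured genes fell, 2 rose and 4 did not pass (10 adjusted over the list alone). VTI12 fell by 0.74, RMR1 by 0.67 and VSR4 by 0.66, and VSR6 rose by 1.18. The list's median was -0.27 (camera adjusted p = 0.0481; adjusted p = 0.501 with an estimated correlation). That call was lost without VSR1 (adjusted p = 0.0852), with quantile normalization (adjusted p = 0.102), with normexp (adjusted p = 0.0642) and without WT replicate 2 (adjusted p = 0.0626). BDG1, an epidermal hydrolase of cutin formation, differed by 0.08 (95% interval -0.02 to 0.19, adjusted p = 0.114) and did not pass, and its sign turned with quantile normalization (-0.04). Of 22 cuticle genes, 12 fell, 6 rose and 4 did not pass (18 adjusted over the list alone; median -0.25, camera adjusted p = 0.083); the wax genes WSD1 and CER1 fell by 2.03 and 1.80, and CER4 rose by 2.60.

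**Figure D4:**
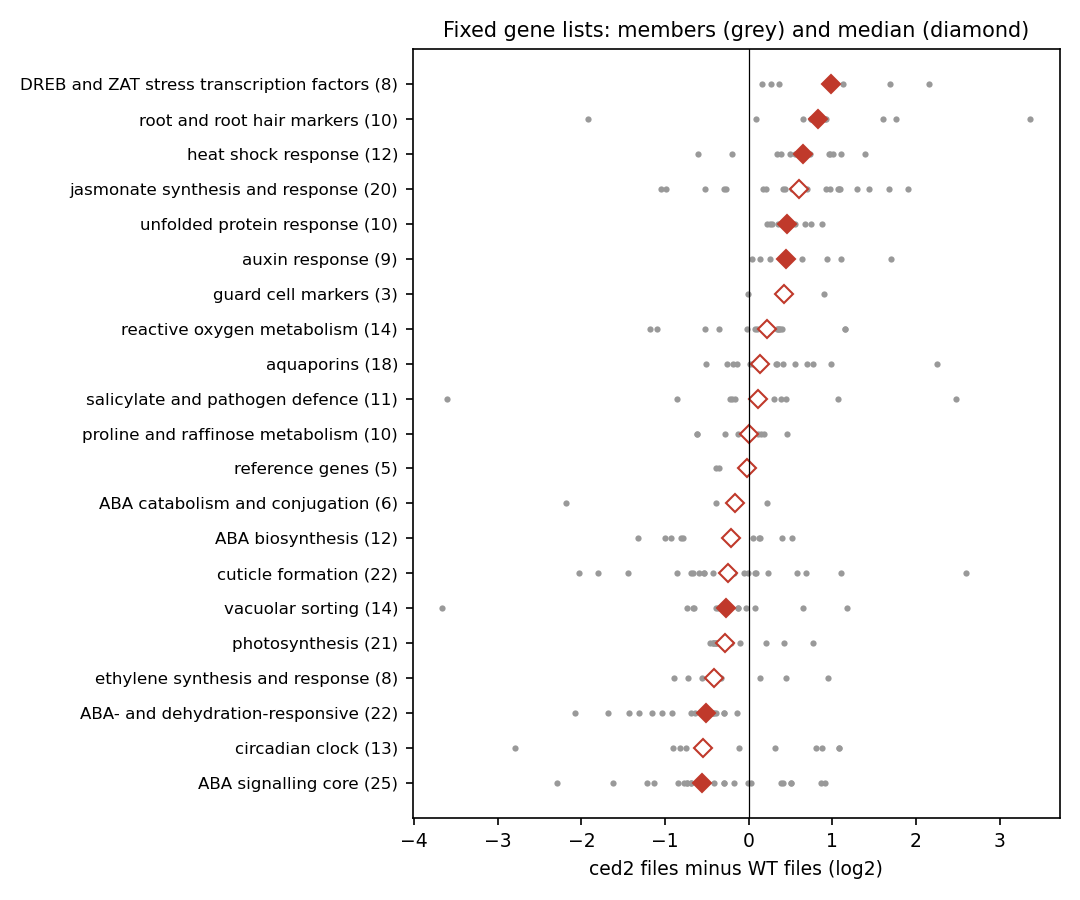
Log2 difference (ced2 files minus WT files) of the measured members (grey points) and their median (diamond, filled where the list passed camera) for 21 fixed lists, with the number measured in brackets. The DREB and ZAT list stands highest at 0.98 and the ABA signalling list lowest at -0.56; proline, photosynthesis and reference gene medians turn sign with quantile normalization, and all turn under the authors' value table.

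The remaining lists did not pass camera in the main setting. Jasmonate genes rose in 15 of 20 and fell in 5 (20 adjusted over the list alone; median 0.61, adjusted p = 0.0619); the signalling repressors JAZ8 and JAZ5 and the lipoxygenase LOX4 rose by 1.68, 1.44 and 1.90, while the storage proteins VSP1 and VSP2 fell by 1.05 and 0.98. This list passed with quantile normalization (adjusted p = 0.0215), with normexp (adjusted p = 0.0134), without a filter on dim probes, with an intensity trend and without WT replicate 1 (adjusted p between 0.0428 and 0.0444 for these 3). Photosynthesis genes fell in 7 of 21, rose in 3 and did not pass in 11 (5 past adjusted over the list alone; median -0.28, adjusted p = 0.071), and their median turned to 0.05 with quantile normalization. Leaving out WT replicate 1 or ced2 replicate 1 brought that list past the threshold (adjusted p = 0.0295 and 0.0272), as did testing without a filter (adjusted p = 0.042). Aquaporins rose in 9 of 18, fell in 2 and did not pass in 7 (11 adjusted over the list alone; median 0.13, adjusted p = 0.138), and PIP2;4 rose by 2.24; the list passed with quantile normalization (adjusted p = 0.0104) and normexp (adjusted p = 0.028).

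Clock genes split, with 5 higher and 8 lower of 13 (13 adjusted over the list alone, median -0.55, camera adjusted p = 0.255). Camera asks for a shift in 1 direction, so it says little about a list that splits. The list was included as a check on harvest time. A difference in harvest time or clock phase between the groups was not tested and cannot be told apart from genotype. The morning genes LHY, RVE8 and CCA1 rose by 1.07, 1.08 and 0.81, and PRR3, ELF4, TOC1 and GI fell by 2.79, 0.82, 0.59 and 0.57. Genes of reactive oxygen metabolism rose in 8 of 14, fell in 4 and did not pass in 2 (12 adjusted over the list alone; median 0.22, adjusted p = 0.472); the oxidase RBOHD rose by 1.15 and the catalase CAT3 fell by 1.18. Ethylene genes fell in 5 of 8, rose in 2 and did not pass in 1 (7 adjusted over the list alone; median -0.41, adjusted p = 0.348), and the synthase ACS6 rose by 0.95. Salicylate and defence genes rose in 6 of 11, fell in 4 and did not pass in 1 (11 adjusted over the list alone, against 10 over all genes). Among them PR1 was at least 5.57-fold higher and PR2 fell by 3.61. The bound for PR1 is simply its measured ratio to a dim WT signal, which lay above the lowest signal well above background. The list's median was 0.11 and its mean -0.02, and the camera test gave lower (adjusted p = 0.953). Proline and raffinose genes rose in 4 of 10, fell in 3 and did not pass in 3 (7 adjusted over the list alone). Both P5CS1 and P5CS2, the synthases of proline, fell by 0.62, the median was 0.007 and the mean -0.07, and the test gave lower (adjusted p = 0.741). Of 3 guard cell markers, 2 rose and 1 did not pass (2 adjusted over the list alone; median 0.42, adjusted p = 0.269), and MYB60 rose by 0.90. The trichome list had 2 measured genes and was not tested: GL2 fell by 2.48 and GL1 by 1.06, in lines that share the gl1 background. Of 5 measured reference genes 1 fell (UBC21, by 0.36) and 4 did not pass (1 past adjusted over the list alone, median -0.02, camera adjusted p = 0.348). Among those 4, UBQ10 was lower by 0.39 (limma adjusted p = 0.0569).

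Camera passed 8 of 21 lists at the preset correlation and 0 with an estimated one, where 0 had an unadjusted p under 0.05. The latter rests on 2 residual degrees of freedom, so it cannot decide whether correlation between genes undoes these calls. The estimate lay below the preset 0.01 for the DREB and ZAT (-0.107), root (-0.072) and auxin (-0.044) lists. So it did for the ABA signalling (-0.030), unfolded protein response (-0.024) and heat shock (-0.004) lists. It lay above for the ABA and dehydration (0.693) and vacuolar sorting (0.074) lists. Limma's fry asks whether a list's genes move one way on balance and not whether they differ from other genes, and it passed 20 of 21.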

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

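The threshold of limma treat and the counts by size alone were chosen after seeing the data, as were the lists without VSR1, without IRT1, and without IRT1 and NRT2.1; the other alternatives were fixed before. Of 52 named genes, 44 kept, where tested, their direction and side of the threshold under the 11 alternatives that were run gene by gene, the authors' value table apart; the stricter thresholds were applied to counts alone. The same held for 13 of 21 lists when the other list tests and left-out members are set aside as well. NCED3 was such a gene, and lay between -1.34 and -1.32 when 1 array was left out (adjusted p between 0.00414 and 0.00666), with the lone array of a group assumed to vary like the other group. The number of genes past the threshold fell from 16239 to 10330 with normexp, run on median intensities, with 616 at least 2-fold higher; the cause was not tested. The median log2 difference over all genes moved from 0.05 to -0.08 with normexp. The number past the threshold lay between 13835 and 15113 with 1 array left out, and was 2360 with a 2-fold minimum. Limma treat against 2-fold called 1223 genes, 884 higher and 339 lower. Counting genes by size alone, with replicate arrays averaged as 1 sample per genotype and no test, gave 2-fold counts within 1.5 times of those reported. This was nearly fixed in advance, because the differences are the same and most genes passed the threshold. It therefore says nothing about whether the replicates are independent. With the replicate block 15684 genes passed and no named gene or list changed its call; same-numbered arrays did not deviate together (r = -0.0136 across probes), so the numbers only name arrays. Slide as a block was not run, since there was 1 slide. Camera with an estimated correlation, on 2 residual degrees of freedom, passed 0 of 21 lists, 0 at an unadjusted p under 0.05 (ABA and dehydration list, median -0.52, adjusted p = 0.536). Fry passed 20, and for the ABA biosynthesis list (median -0.21) it gave an adjusted p of 0.000512. Over the alternatives other than the value table, the median of the ABA and dehydration list lay between -0.592 and -0.299, the latter with quantile normalization. The root list lost its call without IRT1 (median 0.74, adjusted p = 0.0511) and with probes averaged (adjusted p = 0.0587), and its median was 0.53 with normexp; leaving out NRT2.1 as well, the member that fell, was a choice made on its value and decides nothing. The median of the ABA biosynthesis list lay at -0.487 with normexp and -0.137 with probes averaged, and that of ABA catabolism at -0.290 with quantile normalization, -0.285 with normexp, and between -0.272 and -0.107 with 1 array left out. Probes averaged gave medians of -0.344 for the clock, -0.164 for photosynthesis, 0.271 for aquaporins and 0.037 for proline genes, and differences of 2.74 for CYP76C7 and 2.29 for AT3G56180; quantile normalization gave 0.347 for aquaporins. With 1 array left out the photosynthesis median lay between -0.395 and -0.179, BDG1 between 0.046 and 0.123, and the smallest bounds were 22.7-fold for GLC, 8.68-fold for AT5G44973, 7.47-fold for AT3G56180 and 7.42-fold for AT3G45510. Folds of genes with weak signal shrank with normexp, though most kept their call: MRD1 rose by 5.51, bHLH39 by 2.94, CYP82C4 by 1.85 and EXPA18 by 0.948, and the log2 difference was -2.91 for GLC, -2.195 for AT2G04190, -1.97 for AT5G44973, -1.96 for GASA2, -1.914 for AT3G45510, -2.92 for FLC, -3.02 for AT2G02720, -2.67 for HSD1 and -1.19 for NRT2.1. Quantile normalization turned BDG1 to -0.037 and the medians of proline genes to -0.021, photosynthesis genes to 0.049 and reference genes to 0.035. Normexp turned the proline median to -0.058, and the filter on all 4 arrays turned the salicylate median to -0.029. With 1 array left out the proline median lay between -0.0020 and 0.016 and the reference gene median between -0.066 and 0.014. Weak signal limits 12 named genes, which could not be tested with that filter. Under the column labels of the authors' value table, 1666 genes were at least 2-fold lower and 693 higher, and every sign turned, by that table's construction. Among the values that follow, those of GLC, AT2G04190, AT5G44973, AT3G45510, GASA2, NRT2.1, CYP76C7, AT3G56180 and IPT7 rest on a probe that was dim in 1 group. Those of FLC, HSD1 and AT2G02720 rest on a probe dim on 1 ced2 array (FLC at least 21.0-fold, or a fall of 3.29 without that array). None of these values is an exact size. The genes then higher in ced2 were NCED3 at 1.33, VSR1 3.67, GLC 5.73, FLC 4.87, AT2G04190 4.73, AT5G44973 4.63, AT2G02720 4.55, AT3G45510 4.46, GASA2 4.38, HSD1 4.32, ABA3 0.79, BGLU18 1.00, HAI3 2.297, ABI5 1.62, ABF2 1.14, ABI2 1.22, LEA4-5 1.43, RD29B 2.08, EM1 1.68, RD22 1.31, VSR4 0.66, RMR1 0.67, VTI12 0.74 and NRT2.1 1.93. Those then lower were MRD1 at -7.33, CYP76C7 -4.61, bHLH38 -4.53, bHLH39 -4.45, AT3G56180 -4.32, CYP82C4 -4.21, AT1G47395 -4.17, IPT7 -4.06, IRT1 -3.37, CBF2 -2.15, COBL9 -1.76, IAA5 -1.70, DDF1 -1.69, EXPA18 -1.60, HSP21 -1.39, DREB1A -1.12, HSP17.6II -1.11, IAA19 -1.10, HSP23.6 -1.001, ZAT12 -0.97, HSP18.2 -0.96, GH3.3 -0.94, CRT1 -0.74, CNX1 -0.67, BIP2 -0.56, ABA2 -0.51, ERDJ3B -0.51 and BDG1 -0.083. The list medians became 0.56 for ABA signalling, 0.55 for the clock, 0.52 for ABA and dehydration response, 0.41 for ethylene, 0.28 for photosynthesis, 0.27 for vacuolar sorting, 0.25 for cuticle, 0.21 for ABA biosynthesis, 0.17 for ABA catabolism, 0.021 for reference genes, -0.0061 for proline, -0.11 for salicylate, -0.13 for aquaporins, -0.22 for reactive oxygen, -0.42 for guard cell, -0.45 for auxin, -0.46 for the unfolded protein response, -0.61 for jasmonate, -0.64 for heat shock, -0.82 for root and -0.98 for DREB and ZAT genes.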

Other observations

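The iron-deficiency gene list, the tests on it, the tests of the value table and the neighbours of VSR1 were chosen only after the result was seen; the test of inducible genes between replicate arrays was written before its result. Of 24 genes that Arabidopsis induces when iron is short, 22 rose in the ced2 files, 17 of them at least 2-fold, 1 fell and 1 did not pass (limma adjusted p; median 2.05). The list was drawn up because bHLH38, bHLH39, CYP82C4, AT1G47395 and IRT1 stood out; of the 19 genes without these 5, 17 rose and 1 fell (median 1.41, camera p = 3.6e-06, p = 0.101 with an estimated correlation). Besides bHLH38 and bHLH39, the related regulator bHLH100 rose by 3.82, the peptide gene IMA1 by 3.98, the uptake transporter IRT1 by 3.37, the root ferric reductase FRO2 by 2.60 and the regulator FIT by 1.63. PYE fell by 0.54, and BTS, at 0.03, did not pass. The iron storage genes FER1 and FER4 fell by 0.44 and 0.92, and FER3 rose by 0.10. All of these signs turn under the authors' value table.

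VSR1 stood apart from its surroundings: the 16 measured genes nearest to it in gene order, 8 on each side, differed by -0.57 to 0.77 (median -0.08), against -3.67 for VSR1. Among genes at least 2-fold higher in the ced2 files, 140 were not well above background in either WT file, and among those at least 2-fold lower, 108 were dim in both ced2 files.

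The iron-deficiency pattern was weighed against scaling and against root tissue. Scaling between arrays as the whole cause is argued against: the median over the 24 genes fell from 2.05 to 1.86 with quantile normalization and to 1.17 with normexp, still above a bound of 0.5 that was written after the result, and that of the 19 genes was 1.40 and 0.93. A larger share of root in one genotype's seedlings remains open: 9 root markers without IRT1 had a median of 0.74, which lay 1.31 below that of the iron genes (two-sided permutation test, p = 0.0671) and 0.67 below that of the 19 (p = 0.261), so the root share cannot be told apart from a change within roots. A candidate biological explanation is that iron supply or sensing differs between the genotypes under stress, and it is untested, as no iron content or untreated array was used here.

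The conflict of labels was weighed for the value table and for the scanner files. That the table is the scanner data with its sign turned is argued against: the correlation of a column with its own file was as low as -0.573 but not near -1, while each column matched another file at 0.999999. Either the table or the scanner files may carry exchanged genotype labels, and these cannot be told apart here, because the sources used here do not state what ced2 does to NCED3, whose log2 difference of -1.33 follows from the labels chosen. VSR1 and BDG1 were named in advance as genes of known NCED3-promoter mutants, without knowing whether ced2 is among these mutants. VSR1 was 12.7-fold lower in the ced2 files and its neighbours were not. That would be seen if VSR1 were the gene lost in ced2 and the scanner labels right. The mutated gene is not given in the sources used here, so this does not decide. A measurement of the mutated gene in both lines, with its identity stated, would settle it.

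Replicate arrays were closer to each other than repeat spots of a probe within an array. Over 17 bright probes with 5 spots each, the median SD was 0.0433 between the WT arrays and 0.053 between spots of a WT array, and 0.0243 against 0.0462 for ced2; repeat spots also differ in position. One candidate explanation is that both arrays of a genotype carry the same RNA, although the labels call them biological replicates. The 63 measured genes of the heat shock, DREB and ZAT, jasmonate, salicylate and clock lists, which readily differ between plants, differed between replicate arrays no more than random genes of matched signal, at percentiles 35.9 (WT) and 22.8 (ced2) of 10000 random lists, as the same RNA would give. Pools of 20 plants harvested together may also average out such differences, so the p-values measure a spread that is possibly technical alone.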
